A study of Homo sapiens with 6 samples.

How the data were processed

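RNA from HK2 cells was measured in 6 libraries, 3 of total lysate and 3 of FLAG immunoprecipitate, and grouped by their titles, which name the lysates as positive controls. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT), libraries marked strand by dUTP and were sequenced as paired ends. Whether counting used strand is not given in the sources used here, so antisense and overlapping genes are uncertain. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, edgeR, DESeq2 and the build GRCh38.p14, with no role or order. The deposited counts are whole numbers per gene and per transcript, per the file headers. The deposited FPKM values are scaled by length and by library, per the file headers, and served as an alternative scale only. The gene count table held 61806 genes, of which 35253 had a count, and the transcript count table held 251062 transcripts. Library totals are 54363555 to 92948069 counts. The treatment labels number the plasmid from 1 to 6 across samples, while the titles name VMP1 in each immunoprecipitate; the titles were used.

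Differences were tested with edgeR (quasi-likelihood, TMM scaling, its default expression filter, R 4.3.3; edgeR 4.0.16) on the deposited counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are immunoprecipitate minus lysate on the log2 scale, and their SE is the log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM. Transcript usage was tested with diffSpliceDGE and Simes' method. The 27 fixed gene lists hold 934 members, 920 of them found in the gene table, 5 by an older symbol. Lists and gene ontology terms of 15 to 500 tested genes were tested with camera at a preset correlation of 0.01, beside an estimated correlation. Ontology terms came from the deposited gene table. Shares were compared with exact permutation tests. Unchanged libraries were simulated 100 times from the lysate means, at the spread of the lysates and the depth of each library, for the correlation of shifts from the lysate mean; this check was chosen after seeing the data. GC content was not analysed here, as no genome sequence was used.

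Named genes followed a rule set before the data were examined: VMP1, the 12 largest rises and 12 largest falls among called genes with a mean of at least 5 CPM, a symbol and all 3 immunoprecipitates on one side of all lysates, up to 3 members per list by lowest adjusted p (also the lowest of the other direction where a list had calls both ways), and the 4 genes with the lowest p for usage. Of these, 28 genes were eligible as rises and 101 as falls. A fixed list member not printed here is in the counts only, and 1 gene that the rule names is not reported here.

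The code was tested on simulated data. The way the simulation set the spread was changed after its first results were seen: counts drawn from the fitted dispersions gave 0 recovered transcripts, so the spread was then estimated per gene or transcript within groups, and a run at a low dispersion was added. Of 20593 genes drawn at the spread of all 6 libraries, 67, 67 and 66 were changed 2-fold, 4-fold and 8-fold. Of these edgeR recovered 4.48%, 53.7% and 72.7%, with 6 false calls of 93. DESeq2 (version 1.42.0) recovered 41.8%, 86.6% and 90.9%, with 238 false calls of 384. Without FLAG immunoprecipitate 2, over 22062 genes, edgeR recovered 61.2%, 91.0% and 93.9%. For 62534 transcripts at the spread of all 6 libraries edgeR still recovered 0% at each fold size, and for 73009 without FLAG immunoprecipitate 2 it recovered 0%, 0% and 1.52%, so a transcript that was not called may differ. With a low dispersion of 0.05 for the 62534 transcripts of all 6 libraries it recovered 43.3%, 100% and 100%. Usage switches of 8-fold each way were recovered for 26.5% of 200 genes at the spread of all libraries (11292 genes tested) and for 100% at the low dispersion (11558 tested), with 19 and 54 false calls. Without FLAG immunoprecipitate 2 they were recovered for 9% of 200 genes (12126 tested), 18 genes, beside 11 false calls. A list of 40 genes shifted 2-fold was called, and 0 of 26 unshifted lists of random genes were. Each gene was drawn independently there, so this cannot show how often lists of correlated genes are called falsely.

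Alternatives were other scalings (RLE size factors, upper quartile, library totals), other filters, DESeq2, limma (version 3.58.1) on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, subsets of genes, and each library left out in turn. An offset for transcript length, the same with the block, and voom with library weights were chosen after seeing the data. XIST and Y-linked genes were part of the fits and are not reported.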

Results

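HK2 cells, a line of human kidney proximal tubule epithelium, were transfected with a plasmid for FLAG-tagged VMP1, a membrane protein of the endoplasmic reticulum that takes part in autophagosome formation. RNA was collected 48 hours later, either from a FLAG immunoprecipitate or from the total lysate. Each of the 2 groups held 3 libraries. Gene counts summed to between 77753608 and 92948069 per library in the lysates and between 54363555 and 59293096 in the immunoprecipitates. The comparison asks which RNAs were over- or under-represented in the immunoprecipitate relative to lysate. An immunoprecipitate from cells without the FLAG construct was not analysed here, so every value is relative to lysate alone. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

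VMP1 itself (ENSG00000062716, GRCh38.p14 chromosome 17, 59707192 to 59842255, plus strand) was at 302 ± 4.25 CPM (SD, n = 3) in the lysates. It was at 2347 CPM in FLAG immunoprecipitate 1 and at 2685 CPM in FLAG immunoprecipitate 3. In the library labelled FLAG immunoprecipitate 2 it was at 274 CPM, below each lysate. The log2 fold change over all 6 libraries was 2.55 (SE 0.78, edgeR quasi-likelihood adjusted p = 0.156), and without the library labelled FLAG immunoprecipitate 2 it was 3.07 (SE 0.07, edgeR adjusted p = 4.83e-06). Most of the VMP1 signal in immunoprecipitates 1 and 3 was assigned to ENST00000592790, a transcript of 1 exon and 4325 nt annotated as a retained intron (chromosome 17, 59837931 to 59842255). It took 87.4% of VMP1 counts in immunoprecipitate 1 and 78.4% in immunoprecipitate 3, against 42.7%, 42.2% and 46.4% in the lysates and 34.6% in the library labelled FLAG immunoprecipitate 2. Its log2 fold change was 3.17 (SE 1.02, edgeR adjusted p = 0.427) over all 6 libraries and 3.65 (SE 0.09, edgeR adjusted p = 0.00382) without that library. The span of this transcript holds the microRNA gene MIR21 (59841266 to 59841337). The coding transcript ENST00000262291, with 12 exons, was at 172, 177 and 167 CPM in the lysates and at 229, 172 and 460 CPM in immunoprecipitates 1, 2 and 3. The assignment of counts between these overlapping transcripts is an estimate. VMP1 counts can hold RNA from the genome and from the plasmid, which were not told apart here.

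**Figure D1:**
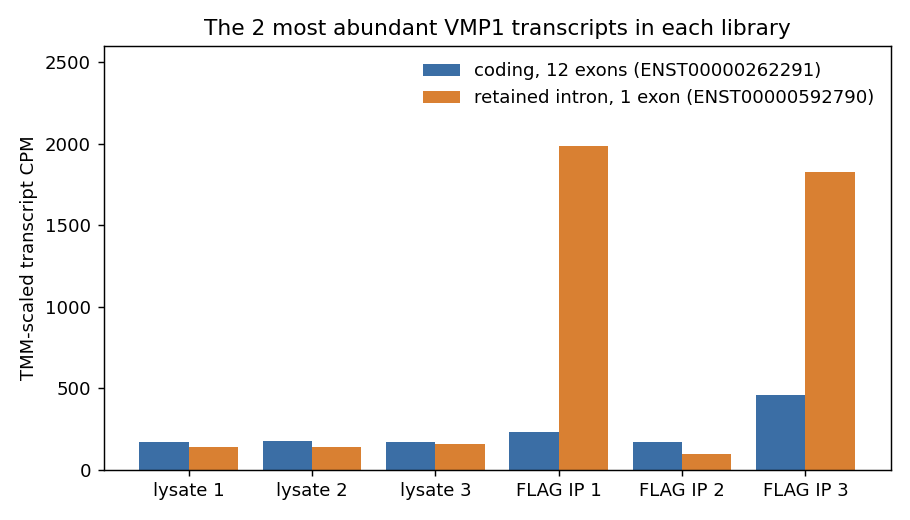
TMM-scaled CPM of the 2 most abundant VMP1 transcripts (y axis) in each of the 6 libraries (x axis), 1 bar per transcript and library. The retained intron transcript reaches 1984 CPM in FLAG IP 1 and 1823 CPM in FLAG IP 3, against 97.6 CPM in FLAG IP 2.

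The library labelled FLAG immunoprecipitate 2 differed from the other two immunoprecipitates across the transcriptome. Over 20593 tested genes, shifts from the lysate mean correlated at r = 0.642 between immunoprecipitates 1 and 3, at 0.053 between 1 and 2, and at 0.016 between 2 and 3. This is a correlation across genes, which are not independent replicates. All 3 shifts are taken from the same lysates, and unchanged libraries simulated against those lysates correlated at 0.236 on average. The covariance was 1.69 between 1 and 3, 0.10 between 1 and 2 and 0.04 between 2 and 3, against 0.05 in the simulation. Lysates correlated with each other at 0.980 to 0.982 on the log2 CPM scale. Values without this library are therefore given beside the main counts.

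**Figure D2:**
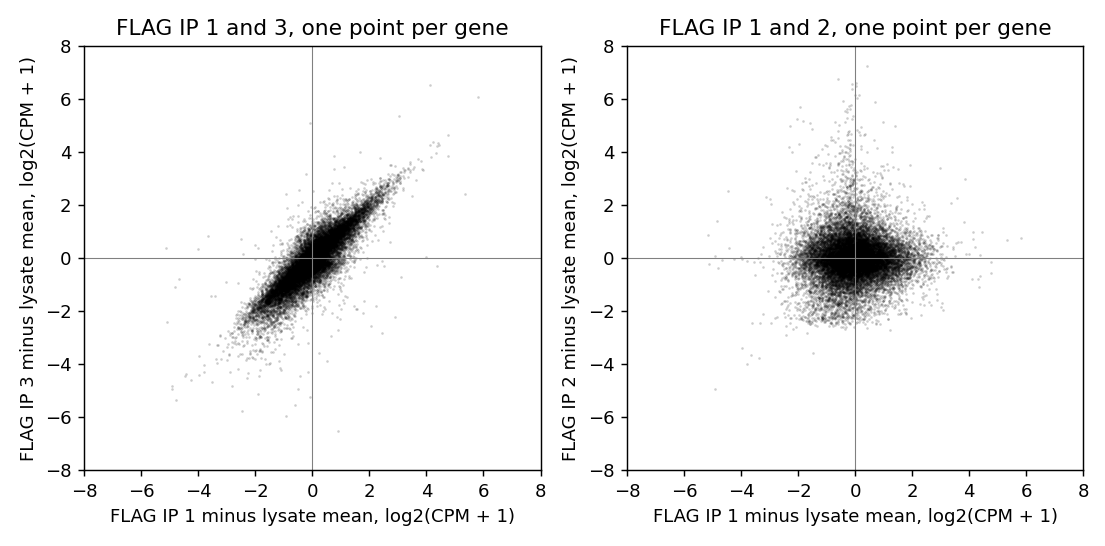
Shift of each gene from the lysate mean, in log2(CPM + 1), in FLAG IP 1 (x axes) against FLAG IP 3 (left, y axis) and FLAG IP 2 (right, y axis), 1 point per gene. Points follow the diagonal on the left and show no common direction on the right.

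The collagen IV genes COL4A1 and COL4A2 of the basement membrane and the fibronectin gene fell in the immunoprecipitate, and 3 small nucleolar RNA host genes and the chromatin gene SS18 rose. Of 20593 genes tested with edgeR, 33 were higher and 103 were lower in the immunoprecipitate at an adjusted p below 0.05, and each of them differed by at least 2-fold. COL4A1 (ENSG00000187498, chromosome 13, 110148963 to 110307157), fell from 1783 ± 66.8 CPM in lysate to 220 ± 96.2 CPM in the immunoprecipitate (SD, n = 3 each), a log2 fold change of -3.02 (SE 0.36, edgeR adjusted p = 0.0387). COL4A2 fell from 1176 ± 27.7 to 151 ± 57.2 CPM (SD, n = 3 each). The ends of these genes overlap on opposite strands, and reads there are uncertain. FN1 (ENSG00000115414), which encodes fibronectin, fell from 10068 ± 749 to 1587 ± 671 CPM (SD, n = 3 each), a log2 fold change of -2.67. CHRDL1, LUM, COL18A1, FOLR1, PTGDS, PSG3, CRTAC1 and LRRN4 were also among the 12 largest falls, with log2 fold changes from -2.80 for PTGDS to -2.40 for LRRN4. PSG3 belongs to a family of near-identical genes and is uncertain.

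SS18, part of a chromatin remodelling complex (ENSG00000141380, chromosome 18, 26016253 to 26091217), rose from 17.9 ± 0.16 to 90.8 ± 9.24 CPM (SD, n = 3 each), a log2 fold change of 2.34 (SE 0.17, edgeR adjusted p = 0.0323). The small nucleolar RNA host genes SNHG17, SNHG26 and SNHG4 rose with log2 fold changes of 2.34, 2.24 and 1.87. FKBP11, a peptidyl-prolyl isomerase of the secretory route, rose from 6.61 ± 0.40 to 26.8 ± 1.02 CPM (SD, n = 3 each). FAM241A, AASS, ABCA5, GSDMB and FER1L4 rose with log2 fold changes between 2.54 for FAM241A and 2.30 for FER1L4, and LINC01106 rose from 2.84 ± 0.19 to 10.6 ± 0.70 CPM (SD, n = 3 each). USP32P1, at 3.79, is a pseudogene whose reads can be shared with its parent gene.

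The counts depended on single libraries. Leaving out any lysate, immunoprecipitate 1 or immunoprecipitate 3 left 0 calls, while 2114 to 3727 genes had an unadjusted p below 0.05. Without the library labelled FLAG immunoprecipitate 2, 5276 of 22062 genes were higher and 5997 were lower, and all 136 genes called over 6 libraries were called in the same direction. DESeq2 called 1942 genes higher and 1213 lower over all 6 libraries. On 20593 genes simulated at this spread it made 238 false calls of 384, against 6 of 93 for edgeR. That simulation changed few genes (67, 67 and 66 at 2-fold, 4-fold and 8-fold) and gave both groups the same spread. The false share there therefore does not carry over to the real calls.

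Fixed gene lists were compared with all other tested genes by camera. With a preset correlation of 0.01, 5 of 27 lists were called higher and 10 were called lower. None was called with an estimated correlation, where the lowest adjusted p was 0.235. Without the library labelled FLAG immunoprecipitate 2, 5 lists were called higher and 17 lower, and 1 and 5 of all lists were called higher and lower with an estimated correlation.

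Secreted and matrix messages had the lowest list median, a log2 fold change of -0.83, with 7 of 42 members lower and 0 higher (camera adjusted p = 6.02e-10, adjusted p = 0.439 with an estimated correlation). Adjusted over the list alone, 14 were lower. NID1, a basement membrane linker, fell with a log2 fold change of -2.17 (SE 0.22), and SPARC, a collagen-binding matrix protein, fell from 1736 ± 42.6 to 397 ± 99.7 CPM (SD, n = 3 each). The median shift from the lysate mean was -1.89 in immunoprecipitate 1, -0.25 in the library labelled 2 and -1.88 in immunoprecipitate 3. Markers of other cell types moved with these libraries. The median shift was -3.51, 0.39 and -4.33 for fibroblast markers, of which the matrix list also holds 3 (COL1A2, COL3A1 and LOX). For neutrophil markers it was -1.96, -0.14 and -3.69. These medians cover the markers that averaged 1 CPM or more in lysate, 9 of 14 fibroblast and 26 of 27 neutrophil markers. Without the library labelled 2 the list median was -1.84, with 35 of 42 members lower (camera adjusted p = 4.96e-27, adjusted p = 0.0219 with an estimated correlation).

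Surface receptors and adhesion molecules gave 3 lower members of 41 and 0 higher, with a median of -0.51 (camera adjusted p = 7.41e-06, adjusted p = 0.589 with an estimated correlation). Adjusted over the list alone, 10 were lower. NOTCH3 fell from 38.2 ± 2.58 to 9.55 ± 1.18 CPM (SD, n = 3 each), and the integrins ITGA3 and ITGAV fell with log2 fold changes of -1.44 and -1.47. Lysosomal genes had a median of -0.80, with 1 of 36 members lower (camera adjusted p = 4.30e-08, adjusted p = 0.59 with an estimated correlation), and 3 lower adjusted over the list alone. The member called was ASAH1, the lysosomal acid ceramidase, which fell from 143 ± 7.35 to 58.8 ± 8.74 CPM (SD, n = 3 each). Without the library labelled FLAG immunoprecipitate 2, 34 of 36 lysosomal members and 33 of 41 surface members were lower. The median shift in immunoprecipitates 1, 2 and 3 was -1.67, -0.17 and -1.48 for the lysosomal list and -1.25, -0.02 and -1.37 for the surface list, in the libraries where the fibroblast and neutrophil markers were also low.

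Glycolytic enzymes had a median of -0.82 and cytoskeletal genes one of -0.63, with 0 members of either called over all genes (camera adjusted p = 6.16e-04 and 5.12e-04, adjusted p = 0.607 for both with an estimated correlation). Adjusted over the list alone, 1 glycolytic and 3 cytoskeletal members were lower. With the library labelled FLAG immunoprecipitate 2 left out, 15 of 17 glycolytic and 29 of 34 cytoskeletal members were lower, 0 and 4 were higher, and the medians were -1.58 and -1.30. The shift in immunoprecipitates 1, 2 and 3 was -1.58, -0.14 and -1.46 for glycolytic and -1.32, 0.09 and -1.33 for cytoskeletal genes. Fibroblast and neutrophil markers were also low in immunoprecipitates 1 and 3. GAPDH was at 7617 ± 332 CPM in lysate and at 1430, 4884 and 1756 CPM in immunoprecipitates 1, 2 and 3, a log2 fold change of -1.50 that was not called (edgeR adjusted p = 0.181). Nuclear genes of oxidative phosphorylation (median -0.57), genes of the NRF2 and ferroptosis list (-0.44), of the translocon (-0.37), of tubular injury (-0.20) and of the proximal tubule (-0.73) were the other lists called lower, and their adjusted p with an estimated correlation lay between 0.235 and 0.69. Over all 6 libraries 1 member of the injury list was lower and 0 members of the other 4 lists were called, and adjusted over the list alone 0, 5, 0, 6 and 2 were lower and 1, on the injury list, was higher. With the library labelled FLAG immunoprecipitate 2 left out, 43 of 50, 21 of 26, 25 of 34, 23 of 32 and 13 of 27 members were lower, in the same order, and 2, 0, 5, 6 and 1 were higher. The medians were then -1.28, -1.19, -0.82, -0.78 and -0.99. All but the proximal tubule list were lower in immunoprecipitates 1 and 3 than in the library labelled 2. For oxidative phosphorylation the shifts were -1.33 and -1.41 against 0.17. Fibroblast and neutrophil markers were low in immunoprecipitates 1 and 3 too. FGB, a fibrinogen chain on the injury list, fell from 39.3 ± 0.79 to 10.5 ± 1.40 CPM (SD, n = 3 each). Proximal tubule genes shifted by -0.82, -2.12 and -1.09 in immunoprecipitates 1, 2 and 3.

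Zinc finger transcription factors had a median of 0.53, with 1 of 77 members higher, ZNF44, and 4 higher adjusted over the list alone (camera adjusted p = 8.77e-07, adjusted p = 0.59 with an estimated correlation). ZNF44 rose from 11.7 ± 0.74 to 34.6 ± 1.95 CPM (SD, n = 3 each). With the library labelled FLAG immunoprecipitate 2 left out, 54 of 77 were higher and 4 lower, with a median of 0.88. Nuclear long noncoding RNAs had a median of 1.18 with 0 of 13 called over all genes and 5 higher adjusted over the list alone (camera adjusted p = 6.16e-04, adjusted p = 0.235 with an estimated correlation). TUG1 was at 209 ± 12.1 CPM in lysate and 497 ± 80.7 CPM in the immunoprecipitate (SD, n = 3 each). Small nucleolar RNA host genes (median 0.58), replication-dependent histones (1.42) and immediate early genes (0.36) were the other lists called higher, with adjusted p of 0.235, 0.593 and 0.589 with an estimated correlation. Over all 6 libraries 1 of 16 host genes on the list, SNHG17, was higher, while SNHG26 and SNHG4 are not on it. For histones 0 of 24 and for immediate early genes 0 of 28 were called. Adjusted over the list alone 2 host genes, 0 histones and 3 immediate early genes were higher. With the library labelled FLAG immunoprecipitate 2 left out, 12 of 16 host genes, 7 of 27 histones and 14 of 28 immediate early genes were higher, 2, 1 and 4 were lower, and 10 of 13 nuclear long noncoding RNAs were higher and 1 lower. The histone list was then no longer called, with a median of 0.77 (camera adjusted p = 0.405). The histone shift was 0.66, 1.96 and 0.26 in immunoprecipitates 1, 2 and 3, and most of its members were near the detection floor.

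Neither list of autophagy, the process VMP1 takes part in, was called by camera over all 6 libraries. The core autophagy list had a median of -0.01 and a mean of 0.11, with 1 of 39 members lower (camera adjusted p = 0.636). That member, GABARAPL1, a protein of autophagosome membranes, fell from 295 ± 23.0 to 122 ± 9.74 CPM (SD, n = 3 each; edgeR adjusted p = 0.0459). The list of autophagosome and lysosome fusion had a median of -0.14 and 0 of 19 members called (camera adjusted p = 0.347). Without the library labelled FLAG immunoprecipitate 2, 9 core members were higher and 16 lower, and 2 fusion members were higher and 11 lower. The fusion list was then called lower, with a median of -0.36 (camera adjusted p = 0.0354, adjusted p = 0.256 with an estimated correlation), and the core list was not (median -0.19, mean -0.20, camera adjusted p = 0.71). Among apoptosis regulators BCL2L1 fell with a log2 fold change of -1.31, and BIRC3, an inhibitor of apoptosis, rose with one of 1.48. Mitochondrially encoded genes had a median of 0.04 over all libraries, with 0 of 13 called, and of -0.52 without the library labelled FLAG immunoprecipitate 2, where the list was called lower (camera adjusted p = 0.00399, adjusted p = 0.454 with an estimated correlation). The list of other cell types had a median of -0.53, with LUM lower, and its shift was -0.79, 0.06 and -2.10 in immunoprecipitates 1, 2 and 3. It was not called over all 6 libraries (camera adjusted p = 0.102). On leaving out the library labelled 2, 9 of 20 members were lower and the list was called lower (camera adjusted p = 0.0135, adjusted p = 0.413 with an estimated correlation). Ribosomal proteins (median -0.33), cytokines and chemokines (0.99), translation factors (-0.10), endoplasmic reticulum chaperones (0.06), interferon response (-0.12), cell cycle (-0.03), apoptosis regulators (0.02) and small structured RNAs (1.01) were not called by camera over all 6 libraries. With the library labelled FLAG immunoprecipitate 2 left out, ribosomal proteins (median -0.63), translation factors (-0.41), chaperones (-0.66) and interferon response (-0.78) were called lower and small structured RNAs (0.67) higher (camera adjusted p = 3.20e-04, 0.0101, 0.00303, 0.0129 and 0.0210). Their adjusted p with an estimated correlation was 0.557, 0.125, 0.122, 0.454 and 0.231. The cytokine list, with shifts of -0.19, 2.02 and -0.56 in immunoprecipitates 1, 2 and 3, turned to a median of -0.45, with 5 members higher and 11 lower, and was not called (camera adjusted p = 0.813). Over all 6 libraries the means of the interferon and cell cycle lists were 0.05 and 0.12, with the opposite sign of the medians, and for apoptosis regulators the mean was -0.04. The test gave a downward direction for the chaperones, whose median and mean were above 0.

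**Figure D3:**
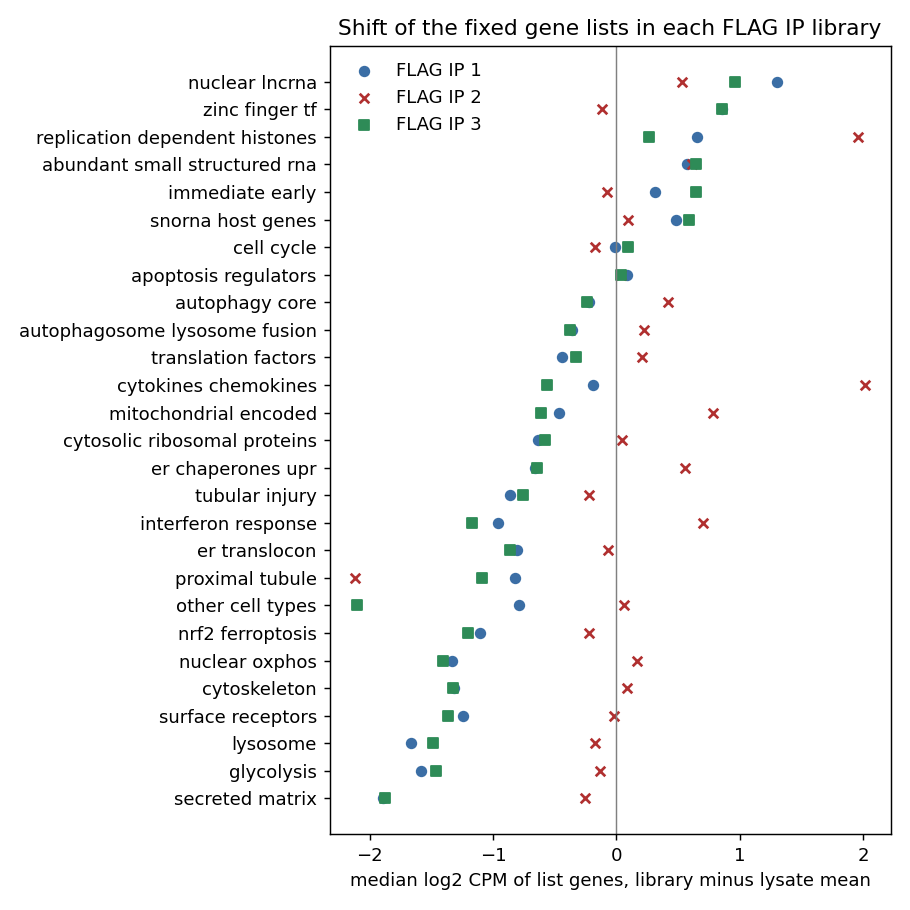
Median log2 CPM of the genes of each fixed list in each FLAG IP library minus the lysate mean (x axis), 1 row per list. FLAG IP 1 and 3 lie close together for most lists, as at -1.89 and -1.88 for secreted and matrix genes, and FLAG IP 2 lies at -0.25 for that list.

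Of 2621 gene ontology terms tested, 35 were called higher and 467 lower by camera. Terms lower included extracellular matrix structural constituent (median -0.88, 107 genes), lysosomal lumen (-0.78, 80 genes) and endoplasmic reticulum lumen (-0.53, 246 genes). A term of neutrophil granules, specific granule membrane (-0.67, 88 genes), was also lower (camera adjusted p = 6.84e-06), beside neutrophil markers at a median of -1.96 and -3.69 and fibroblast markers at -3.51 and -4.33 in immunoprecipitates 1 and 3. Terms higher included nucleosome assembly (0.54, 66 genes), RNA splicing (0.26, 294 genes) and tRNA processing (0.32, 100 genes). With an estimated correlation, the adjusted p of the 16 terms named by the rule, adjusted over 26 terms, lay between 0.0662 and 0.322. These 26 terms were picked by their low camera p, with all 6 libraries or without the library labelled FLAG immunoprecipitate 2. The adjustment does not cover that choice, so an adjusted p below 0.05 in it is not a call. Without the library labelled FLAG immunoprecipitate 2, 64 terms were higher and 750 lower, and tRNA processing was no longer called (camera adjusted p = 0.0971). With an estimated correlation and that library left out, the adjusted p was 0.00781 for extracellular matrix structural constituent, 0.00769 for lysosomal lumen and for endoplasmic reticulum lumen, 0.0406 for nucleosome assembly, 0.0901 for RNA splicing and 0.0754 for tRNA processing and for specific granule membrane. Azurophil granule lumen (-1.19), azurophil granule membrane (-1.15) and ficolin-1-rich granule lumen (-0.97) were also called lower by camera there. The count of lower terms was 170 without immunoprecipitate 1.

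At the level of transcripts, 0 of 62534 were called by edgeR in either direction, while 6044 had an unadjusted p below 0.05. At this spread edgeR recovered 0 of 66 simulated 8-fold changes of transcripts. DESeq2 called 2354 higher and 2468 lower, and edgeR without the library labelled FLAG immunoprecipitate 2 called 1790 higher and 4456 lower. Transcript usage within genes was called different for 271 of 11671 genes. At the spread of all 6 libraries this test recovered 53 of 200 simulated switches, beside 19 false calls. In RNF145, a ubiquitin ligase gene, the transcript ENST00000424310 (11 exons, 3615 nt) was at 64.3, 56.1 and 63.9 CPM in the lysates and had 0 counts in all 3 immunoprecipitates. The transcript ENST00000611185 (12 exons, 3624 nt) had 0 counts in the lysates and took 33.3%, 60.2% and 30.3% of the gene's counts in immunoprecipitates 1, 2 and 3. In ZNF638, ENST00000409544 took 32.1%, 65.6% and 46.8% of the gene's counts in the lysates and 0.0475%, 0% and 0% in immunoprecipitates 1, 2 and 3. OXA1L and STAG3 had the next lowest p. Splits between near-identical transcripts are estimates and are uncertain. The count of genes called for usage was 1469 without the library labelled FLAG immunoprecipitate 2. It was between 13 and 148 without any 1 of the others. Simulated without the library labelled 2, the test recovered 18 of 200 switches, beside 11 false calls. Only 200 genes were switched in each simulation, so its false share does not carry over to the real calls, some of which may be false.

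Long noncoding genes took 1.04 ± 0.02% of gene counts in lysate and 2.07 ± 0.67% in the immunoprecipitate (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). They took 2.46%, 1.30% and 2.44% in immunoprecipitates 1, 2 and 3. Protein-coding genes took 91.6 ± 0.22% and 90.2 ± 0.50% (SD, n = 3 each; exact permutation p = 0.1). The mitochondrial share was 6.47 ± 0.27% and 6.65 ± 0.21% (SD, n = 3 each; exact permutation p = 0.5). Retained intron transcripts took 5.53 ± 0.13% of transcript counts in lysate and 8.75%, 6.04% and 8.77% in immunoprecipitates 1, 2 and 3. The 100 most abundant genes took 21.7 ± 0.27% and 19.9 ± 0.93% (SD, n = 3 each; exact permutation p = 0.1). Genes with at least 10 counts numbered 20942 ± 118 and 20468 ± 1110 (SD, n = 3 each; exact permutation p = 0.8). After thinning to the lowest total they numbered 19516 and 20373, the opposite order. Spearman's rho across genes of log2 fold change was -0.0008 with transcript length and -0.16 with mean level, and the latter was -0.0736 without the library labelled FLAG immunoprecipitate 2.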

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

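The counts of called genes moved most with the library labelled FLAG immunoprecipitate 2 and with the test. Leaving out each library in turn gave from 0 to 5276 genes higher and from 0 to 5997 lower, from 0 to 1790 transcripts higher and from 0 to 4456 lower, from 13 to 1469 genes with a usage change, from 9 to 17 lists called lower, from 18 to 64 ontology terms higher and from 170 to 750 lower, and VMP1 log2 fold changes of 2.11 to 3.07; the highest values are those without the library labelled FLAG immunoprecipitate 2. Genes higher and lower numbered 7 and 33 with no filter, 127 and 210 with at least 1 CPM in all 6 libraries, 17 and 46 with a length offset, 1942 and 1213 with DESeq2, and 4806 and 5370 with voom and library weights; 21 were higher with limma on log2(FPKM + 1). DESeq2 gave 2354 and 2468 transcripts. Usage changes numbered 34 with at least 1 CPM in all libraries and 428 by the gene-level F test. With an estimated correlation 0 lists were called higher and 0 lower, and with fry 3 and 1. VMP1 was called with DESeq2 (2.61) and with library weights (2.93). By FPKM the protein-coding share differed by -3.00 points and the mitochondrial by 1.16. Genes detected differed by -2194 at a minimum of 1 count, by 857 after thinning to the lowest total and from -884 to 158 on leaving out each library, the last without FLAG immunoprecipitate 3. The rho with length was 0.0822 at 1 CPM in all libraries, against -0.0008. The mitochondrially encoded list had medians of -0.52 to 0.31 on leaving out each library, and was called lower at -0.52, without the library labelled FLAG immunoprecipitate 2. The median log2 fold change of all genes was 0.06 with TMM and 0.19 with library totals. The cause was not tested for any of these. Length offsets and library weights were chosen after seeing the data. The planned correction for GC content was not run. The biological coefficient of variation of genes was 0.598 over 6 libraries and 0.378 without the library labelled FLAG immunoprecipitate 2.

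With the replicate number as a block, 0 genes were called higher and 0 lower by edgeR, with 2658 at an unadjusted p below 0.05. With a length offset as well, 0 were called and 2614 had such a p. With the block 0 genes had a usage change. Same-number deviations from the group means correlated at -0.011, -0.054 and 0.010. The lysates differed little from each other, so their deviations leave little for a shared culture to show. This check therefore cannot tell whether the numbers pair the samples.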

Other observations

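The tests of what sets the library labelled FLAG immunoprecipitate 2 apart and of red cell markers were chosen after the values were seen. Without that library, ontology terms of the centriole (median log2 fold change 0.29), centrosome duplication (0.93) and kinetochore assembly (0.76) were called higher in the immunoprecipitate (camera adjusted p = 1.29e-05, 5.22e-05 and 6.40e-04), and focal adhesion (-0.83) lower (7.42e-14). Over all 6 libraries their camera adjusted p was 0.0676, 0.0410, 0.125 and 8.26e-05, and 0.329, 0.214, 0.334 and 0.322 with an estimated correlation, so none was called in that way. With an estimated correlation and without that library, their adjusted p over 26 terms was 0.0227, 0.0293, 0.0364 and 0.00769. These terms were picked by their low camera p in that same fit, so these values do not count as calls. In all 6 libraries, 103 transcripts were at 5 CPM or more in each lysate with 0 counts in each immunoprecipitate, and 6 the other way round; the highest sum in another split was 59. Of the 271 genes called for usage, 67 held such a transcript.

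The library labelled FLAG immunoprecipitate 2 had VMP1 near the lysate level. Lysate RNA carried through without enrichment, as the only source, is argued against. In this library 6493 genes were over 2-fold apart from the closest lysate, against at most 1768 between lysates. It was still nearer to that lysate (correlation 0.917) than to immunoprecipitates 1 and 3 (0.840 and 0.806). Lysate RNA mixed with other RNA therefore stays open. A swap with a lysate is argued against too. The lowest correlation between lysates was 0.980, above the highest of any lysate with an immunoprecipitate, the same 0.917. RNA of other cells or of another culture state may have entered, as 100 genes were at 20 CPM or more in this library and under 10% of that elsewhere, against at most 1 in any other library. Among them, chosen after their values were seen, were C3 (2419 CPM, at most 70.9 elsewhere), COL5A1 (493, at most 9.10) and DHRS2 (290, at most 2.08); no biological explanation was tested, and other cells and another culture state stay open.

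Transcripts known from neutrophils were present in the lysates and the library labelled FLAG immunoprecipitate 2 of a kidney epithelial line. FCGR3B was at 126, 66.2 and 70.5 CPM in the lysates, and at 14.9, 99.2 and 0.61 in immunoprecipitates 1, 2 and 3, and CSF3R and S100A9 averaged 100.8 and 97.1 CPM in the lysates; these were chosen after their values were seen. RNA of neutrophils is a candidate source. Of 27 further markers listed before their values were seen, 96.3% averaged 1 CPM or more in the lysates. Of 16 lymphocyte, 14 fibroblast and 13 red cell markers, 100%, 64.3% and 38.5% did so, so the bar does not single out neutrophils. Shifts were taken only over markers at that bar, 26 of the 27 neutrophil markers. Their median log2 shift was -1.96, -0.14 and -3.69 in immunoprecipitates 1, 2 and 3. Whole blood is argued against as one source. In immunoprecipitate 3 the median shift was -0.08 for the 5 red cell markers at 1 CPM or more. That was 3.61 above the median of the 26 neutrophil markers at the bar among those listed in advance. It was 5.18 above the -5.26 of 13 neutrophil markers picked after their values were seen. At the same bar, 16 lymphocyte markers shifted by -0.99, -0.15 and -1.98 and 9 fibroblast markers by -3.51, 0.39 and -4.33. A wider mix therefore stays open, as do reads of another sample sequenced alongside, which were not analysed here.

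In immunoprecipitates 1 and 3, secretory messages were low and zinc finger messages high. Transcript length is argued against, as zinc finger and secreted messages differed little in it, with median lengths of 4545 and 5414 nt. For that reason a length offset could change little, and it left 100.1% of the gap of 2.72 between the medians of both lists. A higher share of nuclear RNA may account for part of it, as retained intron transcripts rose against coding transcripts of the same gene by a median log2 difference of 1.70 in immunoprecipitate 1 and 1.75 in immunoprecipitate 3, over 3580 genes, against 0.39 in the library labelled FLAG immunoprecipitate 2; the share of retained introns per library had been seen before this test. The secretory shift went with that of fibroblast and neutrophil markers, so a loss of RNA of other cells stays open for part of it. Binding to VMP1 and unspecific binding to the beads stay open as untested, since an immunoprecipitate without FLAG was not analysed here.

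The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 136 genes and the highest other 0, so 1 of 10 splits, the real one, gave as many. For usage the real count was 271 and the highest other 78, and again 1 split gave as many. For transcripts both were 0, so all 10 splits gave as many. For lists the real count was 15 and the highest other 19, with 4 splits as large, the real one included, and for ontology terms it was 502 against 629, with 3 as large. The splits with 16 to 19 lists set FLAG immunoprecipitates 1 and 3 together on one side and the library labelled 2 on the other, which points to a structure of the samples.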
